A study of Mus musculus with 6 samples.

How the data were processed

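RNA was measured by sequencing in 6 libraries of mouse splenic B lymphocytes, 3 labelled as wild type (WT) and 3 labelled as knockout (KO) for GPR40, the fatty acid receptor encoded by Ffar1. Per the labels' protocols, B cells were enriched from spleen by magnetic negative selection, which removes other cells and leaves B cells untouched. Per the same protocols, mRNA was captured with oligo(dT), copied with random hexamers and sequenced in paired ends on a BGISEQ-500. No step that marks the strand is stated, so reads of overlapping genes on opposite strands cannot be separated.

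Each gene and each transcript came with estimated counts that the authors deposited without scaling to depth, per the file headers. Of the gene values, 5.87% were not whole numbers. The authors also deposited FPKM, scaled to gene length and depth, and TPM, scaled to a fixed sum of transcripts, per the file headers. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.3.1, without their roles, and the mm10 build. Filters applied before deposit are not given in the sources used here. A further 12 columns of values per library, whose unit could not be settled, were not used.

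The estimated counts were rounded to whole numbers, and each column was assigned to a library by its name. Totals lay between 14907080 and 15461425 counts per library. A count of 3 was taken as the floor, the upper limit that a count of 0 allows, and came to about 0.2 CPM, the count scaled to library size. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Counting intervals are exact at 95%.

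Genes were filtered with the defaults of edgeR 4.0.16 (filterByExpr by group), which left 12234 of 16511 genes and 31150 of 55379 transcripts. TMM factors were used for scaling. The main test was edgeR's quasi-likelihood F-test with robust dispersion on the label alone, adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Adjusted p-values below come from this test unless another is named. The labels number the replicates but do not say that they came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

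The labels give both groups the replicate numbers 1 to 3. Deviations from the group means were correlated across genes between same-numbered libraries, with r = 0.133, 0.362 and 0.170, and each library correlated best with its own number. All 3 values are above 0.1, so the numbers were treated as a possible pairing in an alternative fit only. The main test did not use them. Deviations within a group sum to 0, so some correlations between the groups must be positive. The values therefore do not establish the pairing. This pairing comes from the data and not from the labels. A fit with the replicate number as a block was run beside the main one, and its values are given where they change a call or move a count of calls in either direction by more than 1.5 times, for the genes and lists named.

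Before the data were examined, 41 gene lists were fixed for B cell types, receptor and stress pathways, metabolism, RNA quality and the other cell types of spleen. Lists with at least 5 tested members, 37 in all, were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. For each list, members were also adjusted over the list alone. The lists of immunoglobulin constant genes, mitochondrially encoded genes, mast cell and basophil markers and sex-linked genes had fewer than 5 tested members and are not analysed here.

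The genes named in the text were chosen by a rule fixed at the same time. It takes Ffar1 in every library, the 12 largest rises and 12 largest falls among called genes without overlap between groups and with a mean of at least 1 CPM, up to 4 members of smallest p from each list, and called neighbours of Ffar1. Antigen receptor segments, unnamed gene models and pseudogenes were left out of the largest changes. Genes named outside this rule, such as Syk, S100a9 and Hba-a1, were chosen after their values were seen. Some genes that the rule takes are not reported here. Coordinates are from GENCODE and RefSeq annotations of GRCm38, the same build as mm10; 16401 of the 16511 gene identifiers matched the RefSeq table.

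The procedures were tested on simulated counts with 200 changed genes, drawn from the means and library sizes of these libraries. Among 12234 simulated genes, the main test recovered 20.9% of genes changed by 1.5-fold, 65.7% changed by 2-fold and 86.4% changed by 4-fold, with 3 false calls. Among 31150 simulated transcripts it recovered 2.99% of those changed by 2-fold and 13.6% of those changed by 4-fold, with 4 false calls. Camera and fry each recovered 3 of 3 shifted lists with 0 false calls. The simulated genes varied independently of each other. In these libraries the estimated correlation was 0.80 among ribosomal protein genes and 0.91 among erythroid markers. The simulation therefore cannot show how often lists of correlated genes are called falsely.

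Alternatives fixed at the same time were other scaling factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter at a mean count of 50, dispersion without the robust option, limma-trend on log2 FPKM or TPM with pseudocounts of 1 or 0.1, a size threshold of 1 on the log2 scale, the replicate block, and the removal of each library in turn. A fit without the libraries labelled WT replicate 1 and labelled KO replicate 3, which stand apart from the rest, was added after seeing the data. All 10 splits of the 6 libraries into 3 and 3 were also tested.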

Results

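Gene expression was measured by RNA sequencing in B lymphocytes enriched from the spleens of mice labelled GPR40-WT or GPR40-KO, with 3 libraries per group. GPR40, the product of Ffar1, is a G protein-coupled receptor for free fatty acids. Depth was even, between 14907080 and 15461425 estimated counts per library. The first principal component of the 500 most variable genes held 47.7% of their variance and placed the 3 libraries labelled WT on one side and the 3 labelled KO on the other. No pair of replicates agreed within sampling noise, since chi-square per degree of freedom lay between 12.3 and 48.3.

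The targeted gene went against the labels in all 6 libraries. Ffar1 had 0 counts in each of the 3 libraries labelled WT and 273, 392 and 304 counts in the libraries labelled KO replicates 1, 2 and 3. This corresponds to 21.6 ± 4.0 CPM (SD, n = 3) in the libraries labelled KO, at least 110-fold higher than the floor of 3 counts per library in those labelled WT (edgeR adjusted p = 2.07e-04). Because of this, groups are named by their labels throughout, and every direction below is that of the label and not of a verified genotype. Column names and sample titles carried the same group for each library.

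Both tested genes that flank Ffar1 differed as well, in opposite directions. Ffar1 lies on chromosome 7 at 30857390 to 30861564 (GRCm38, minus strand) and has 1 annotated exon. Ffar3, a receptor for short-chain fatty acids that lies 1212 bp from Ffar1, fell from 40.2 ± 7.72 CPM in the libraries labelled WT to 0.982 ± 0.104 CPM in those labelled KO (SD, n = 3, log2 fold change -5.34 ± 0.21, SE, adjusted p = 1.93e-05). Cd22, an inhibitory coreceptor of B cells 3838 bp away on the other side, rose from 758 ± 128 to 1680 ± 139 CPM (log2 fold change 1.15 ± 0.13, adjusted p = 0.00244). Ffar2, at a distance of 33615 bp, had a log2 fold change of -1.27 ± 0.62 and did not pass (adjusted p = 0.219). Of the 9 tested genes in the list of Ffar1 neighbours, Cd22 rose, Ffar3 fell and 7 did not pass, with the same counts when adjusted over the list alone, the list had a camera adjusted p of 0.788. With the replicate block, 2 neighbours were lower in the libraries labelled KO, Fxyd5 being the added one (blocked adjusted p = 0.0182).

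**Figure D1:**
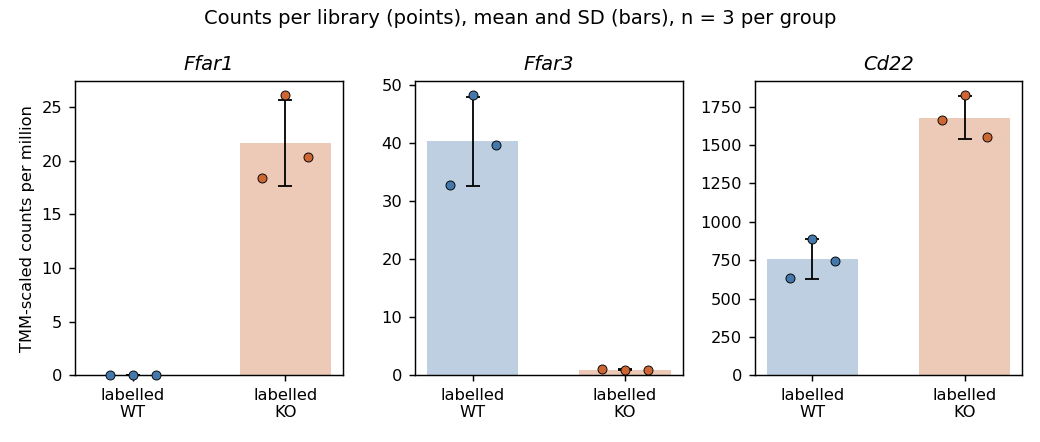
TMM-scaled CPM of 3 genes in the libraries labelled WT and labelled KO, with each axis starting at 0; points are libraries, bars are means and whiskers are SD (n = 3). Ffar1 is at 0 in all 3 libraries labelled WT and at a mean of 21.6 in those labelled KO, while Ffar3 is at 40.2 and 0.982.

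**Figure D2:**
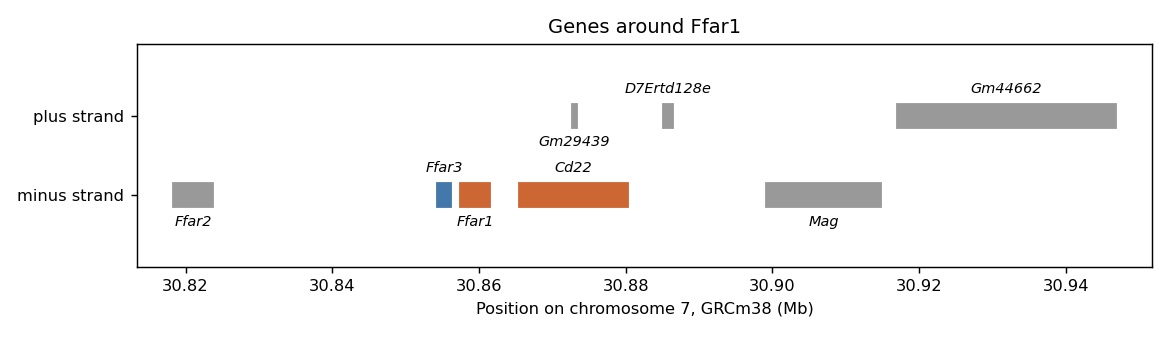
Genes around Ffar1 on chromosome 7 (GRCm38, position in Mb) by strand. Ffar1 and Cd22, higher in the libraries labelled KO, are orange; Ffar3, lower in them, is blue; genes in grey were not called or not tested.

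Across 12234 tested genes, 1146 were called, of which 557 were higher in the libraries labelled KO and 589 in those labelled WT. With the replicate block 2535 genes were called, 974 higher in the libraries labelled KO and 1561 in those labelled WT, and 1138 genes were called in both fits. At least a 2-fold difference was seen for 449 called genes, 124 higher in the libraries labelled KO and 325 in those labelled WT. The groups did not overlap for 33.4% of tested genes, where chance gives 10%. Each library weighed on the count, which was 704, 2030 and 528 without the libraries labelled WT replicates 1, 2 and 3, and 380, 264 and 623 without those labelled KO replicates 1, 2 and 3. The count was 567 without the libraries labelled WT replicate 1 and labelled KO replicate 3 together, an alternative chosen after seeing the data.

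After Ffar1, the large rises in the libraries labelled KO that are named here were of genes near 0 in those labelled WT. Fras1, an extracellular matrix protein of basement membranes, had 1 count in the libraries labelled WT against 441, a ratio of 451 (95% counting interval 80.5 to 17853). AF067061 had 2 counts against 92, a ratio of 47.0 (12.7 to 394). Ngfr, the low-affinity neurotrophin receptor, rose to 10.6 ± 0.80 CPM from 0.219 ± 0.152 (log2 fold change 5.55 ± 0.44), and Sv2b, a synaptic vesicle protein, had a log2 fold change of 4.78 ± 0.45. Zbtb32, a transcriptional repressor of lymphocytes, rose to 14.6 ± 2.77 CPM from 0.916 ± 0.342. It lies near Ffar1 on chromosome 7, at 30589680 to 30602819, where Ffar1 starts at 30857390. Whether its rise is tied to the Ffar1 locus was not tested. Etl4 and Ifng rose by 4.18 ± 0.78 and 4.09 ± 0.82 on the log2 scale. The muscle genes Igfn1, Klhl41 and Ryr1 had log2 fold changes of 4.82 ± 1.11, 4.62 ± 1.17 and 4.44 ± 1.00, with Ryr1 at 379 counts in the library labelled KO replicate 3 and 65 and 71 in the other replicates; Ryr1 was not called with the replicate block (blocked adjusted p = 0.0604). Etl4 was not called without the library labelled WT replicate 1, or labelled KO replicate 1 or 2 (adjusted p up to 0.0940). Ifng and Igfn1 were not called without the library labelled WT replicate 3, or labelled KO replicate 1 or 2 (adjusted p up to 0.112 and 0.130). Klhl41 was not called in any of the 6 fits without 1 library (adjusted p up to 0.123). Ryr1 was not called without any 1 of the libraries labelled WT, or that labelled KO replicate 1 or 2 (adjusted p up to 0.155). Without the library labelled WT replicate 1 the log2 fold change of Igfn1 was 8.33, and without that labelled KO replicate 3 that of Klhl41 was 3.06.

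Genes with the largest falls in the libraries labelled KO included several of myeloid cells. After Ffar3, the amino acid transporter Slc6a19 fell from 19.2 ± 3.56 to 1.05 ± 0.39 CPM (log2 fold change -4.18 ± 0.31). The aquaporin Aqp9 had a log2 fold change of -4.08 ± 0.52. Cstdc4 had 2 counts in the libraries labelled KO against 180, a ratio of 88.0 (95% counting interval 24.0 to 732). Alox5, the leukotriene-forming lipoxygenase, Tlr5, the flagellin receptor, and Cd101 had log2 fold changes of -3.92 ± 0.82, -3.93 ± 0.71 and -3.86 ± 0.85. The T cell coreceptor chain Cd8b1, Dach1, Lin28a and Klk8 lay between -4.45 and -3.72. The receptor tyrosine kinase Ret had -3.75 ± 0.52 and was not called with the replicate block (blocked adjusted p = 0.0629). Of the 23 largest changes named here, 9 passed in every fit that left out 1 library, namely Ffar1, Fras1, Ngfr, AF067061, Sv2b, Zbtb32, Ffar3, Slc6a19 and Aqp9. Cstdc4 and Lin28a were not called without the library labelled WT replicate 1, or any 1 of those labelled KO (adjusted p up to 0.136 and 0.138). Alox5, Tlr5, Cd101 and Cd8b1 were not called without any 1 of the libraries labelled KO (adjusted p up to 0.169, 0.0694, 0.159 and 0.162). Dach1 was not called without the library labelled WT replicate 1, or labelled KO replicate 1 or 2 (adjusted p up to 0.112). Klk8 was not called without the library labelled WT replicate 1 or 3, or any 1 of those labelled KO (adjusted p up to 0.119). Ret was not called without the library labelled KO replicate 2 (adjusted p = 0.0826). Cd101 was at -2.53 without the library labelled WT replicate 1.

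**Figure D3:**
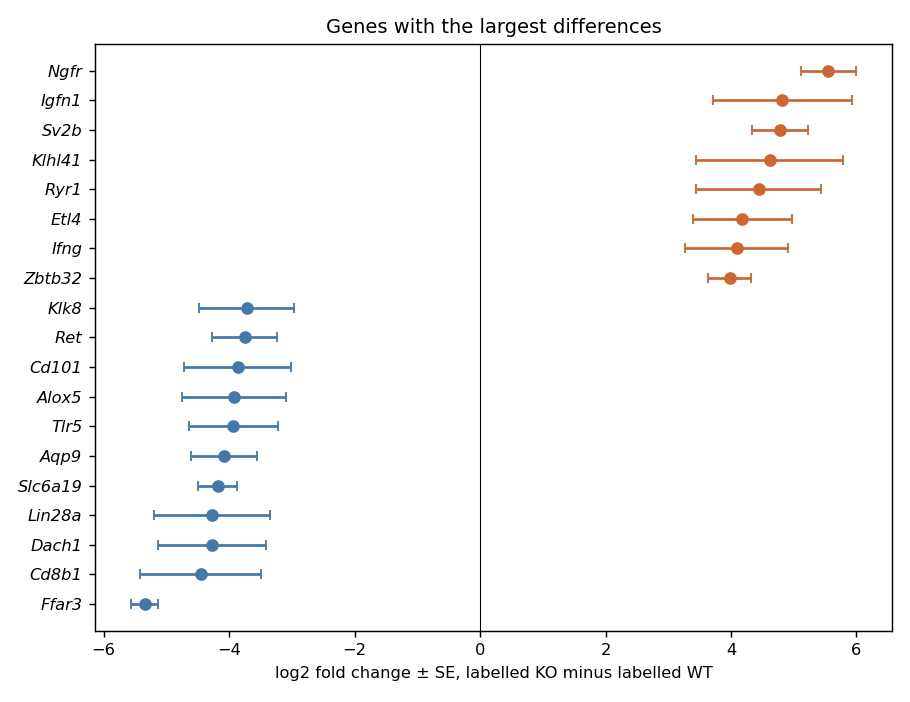
Log2 fold changes (libraries labelled KO minus labelled WT, n = 3 each) with SE for the genes with the largest differences; genes with 3 or fewer counts in a group are left out. Ffar3 is at -5.34.

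Genes of mature B cells were on balance higher in the libraries labelled KO. In the list of pan-B and follicular genes, 11 of 27 tested members rose, 1 fell and 15 did not pass (13 and 4 adjusted over the list alone, 15 and 4 with the replicate block), with a median log2 fold change of 0.35. The BAFF receptor Tnfrsf13c rose by 1.32 ± 0.09, Fcrla by 1.22 ± 0.08 and Cd72 by 1.13 ± 0.10, while Syk was the member that fell. Fcer2a, Pou2af1 and Ccr7 were lower by 0.51, 0.54 and 0.40 without passing (adjusted p = 0.0709, 0.0859 and 0.0872). These 3 passed adjusted over the list alone and with the replicate block (blocked adjusted p = 0.00384, 0.0343 and 0.0131). Cd79a, which encodes a signalling chain of the B cell receptor, had 1995 ± 464 and 2545 ± 138 CPM and did not pass (log2 fold change 0.35 ± 0.16, adjusted p = 0.190), although it passed with the replicate block (blocked adjusted p = 0.0358). The list was called by camera (adjusted p = 2.88e-06) and not with an estimated correlation (adjusted p = 0.591 with an estimated correlation). Among genes of B cell receptor and calcium signalling, 10 of 29 rose, 2 fell and 17 did not pass (17 and 2 adjusted over the list alone, 16 and 2 with the replicate block), with the phosphatase Ptpn6 at 1.41 ± 0.08 and the phospholipase Plcg2 at 0.73 ± 0.09. Its camera adjusted p was 1.50e-07 (adjusted p = 0.585 with an estimated correlation). In the same comparison, the medians of neutrophil, macrophage and T cell markers were -3.91, -1.47 and -2.81.

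Marginal zone genes showed 4 rises and 1 fall among 18 tested members, with 13 not passing (5 and 1 adjusted over the list alone, 5 and 2 with the replicate block). Dtx1, a regulator of Notch signalling, rose from 36.4 ± 2.00 to 120 ± 11.9 CPM, and the complement receptor Cr2 from 71.4 ± 10.8 to 209 ± 23.1 CPM. Ccr6 rose by 1.03 ± 0.14 on the log2 scale, whereas Asb2 fell by 1.08. The list passed camera (adjusted p = 0.0425, and adjusted p = 0.585 with an estimated correlation) but not with the replicate block (blocked adjusted p = 0.0779), nor without the library labelled WT replicate 1 or that labelled KO replicate 3 (adjusted p up to 0.0889). Of 26 genes of antigen presentation and costimulation, 9 rose, all of the MHC class II pathway, 1 fell and 16 did not pass (11 and 4 adjusted over the list alone, 11 and 4 with the replicate block). Ciita, the class II transactivator, rose by 0.89 ± 0.12 and H2-Eb1 by 0.86 ± 0.12; the list as a whole did not pass (camera adjusted p = 0.112). Asb2 was not called without the library labelled KO replicate 2 (adjusted p = 0.0762). Neutrophil and macrophage markers had medians of -3.91 and -1.47 in this comparison.

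Genes of transitional and immature B cells were on balance lower in the libraries labelled KO. In this list 4 of 11 members fell and 7 did not pass (0 higher and 7 lower adjusted over the list alone, 2 lower with the replicate block), with a median of -1.46 (camera adjusted p = 6.94e-05, and adjusted p = 0.388 with an estimated correlation). The median is the value of Erg, which had 3.35 ± 2.04 and 1.21 ± 0.75 CPM and did not pass (adjusted p = 0.199). Cd93 fell by 0.82 on the log2 scale and Sox4 by 0.71. Cd24a went the other way without passing (0.13 ± 0.14, adjusted p = 0.599). The recombinase genes Rag1 and Rag2 fell from 449 ± 160 to 87.1 ± 24.7 CPM and from 22.9 ± 11.4 to 4.69 ± 1.28 CPM, but neither was called with the replicate block (blocked adjusted p = 0.114 and 0.0585). Sox4, Rag1 and Rag2 were not called without the library labelled WT replicate 3, or any 1 of those labelled KO (adjusted p up to 0.103, 0.108 and 0.145). Medians of neutrophil, macrophage and T cell markers were -3.91, -1.47 and -2.81 beside this list.

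Lists of B-1, germinal centre and plasma cell genes were not called. B-1 genes had 2 rises, Zbtb32 and Ptpn22, and 10 of 12 members not passing (2 and 2 adjusted over the list alone, 2 and 2 with the replicate block, camera adjusted p = 0.430). Among 13 germinal centre genes, Tnfrsf13b and Mybl1 rose, Rgs13 and S1pr2 fell and 9 did not pass (3 and 3 adjusted over the list alone, 3 and 4 with the replicate block, camera adjusted p = 0.705); the median was 0.30 and the mean -0.14. Among 19 plasma cell genes, Txndc5 and Sdc1 rose, Prdm1 and Cd93 fell and 15 did not pass (3 and 4 adjusted over the list alone, 3 and 5 with the replicate block, camera adjusted p = 0.863). Prdm1, the transcription factor that drives antibody secretion, went from 92.7 ± 15.2 to 26.0 ± 3.31 CPM. S1pr2 was not called without the library labelled WT replicate 1 or 3, or any 1 of those labelled KO (adjusted p up to 0.127).

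Activation and stress genes were on balance lower in the libraries labelled KO. Of 27 immediate early genes, 9 fell, 2 rose and 16 did not pass (13 and 2 adjusted over the list alone, 13 and 3 with the replicate block), with a median of -0.65; Klf6 fell by 0.92, Gadd45b by 0.95 and Dusp5 by 0.80, and Ier5 rose by 0.67 ± 0.09. The list had a camera adjusted p of 5.17e-04 (adjusted p = 0.585 with an estimated correlation). Of 25 NF-kB targets and regulators, 7 fell, 1 rose and 17 did not pass (17 and 2 adjusted over the list alone, 13 and 2 with the replicate block), with Bcl3 at -0.78 ± 0.10, Birc3 at -0.52 ± 0.09 and Nfkb1 the member that rose (camera adjusted p = 2.88e-06, and adjusted p = 0.585 with an estimated correlation). Of 25 genes of the type I interferon response, 2 fell, Bst2 and Ifih1, and 23 did not pass (2 adjusted over the list alone), while 21 fell with the replicate block; the median was -1.20, and -0.61 without the library labelled WT replicate 1 (camera adjusted p = 7.26e-06, and adjusted p = 0.608 with an estimated correlation). Birc3 was not called without the library labelled KO replicate 1 (adjusted p = 0.0779). Bst2 and Ifih1 were not called without the library labelled WT replicate 3, or any 1 of those labelled KO (adjusted p up to 0.154 and 0.146). Markers of other blood cells were lower in the same comparison, with medians of -3.91 for neutrophil, -1.47 for macrophage and -2.81 for T cell markers. As medians relative to each gene's mean, the libraries labelled WT replicates 1, 2 and 3 had 0.45, 0.02 and 0.33 for immediate early, 0.36, 0.04 and 0.22 for NF-kB and 1.21, 0.40 and -0.20 for interferon genes. The same libraries had 0.94, -0.12 and 1.29 for macrophage, 3.43, 1.70 and 0.20 for neutrophil and 3.00, 0.60 and -0.33 for T cell markers.

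In the unfolded protein response, 4 of 24 genes fell and 20 did not pass (5 adjusted over the list alone, 7 with the replicate block), among them Trib3 at -1.04 ± 0.14 (camera adjusted p = 3.35e-04, and adjusted p = 0.585 with an estimated correlation). Of 14 heat shock genes, Hspa8 fell and 13 did not pass (0 adjusted over the list alone, 2 with the replicate block). The heat shock list was called (camera adjusted p = 0.00949, and adjusted p = 0.608 with an estimated correlation) but not without the library labelled WT replicate 3 (adjusted p = 0.153), which moved its median from -0.29 to -0.11 and that of the unfolded protein response from -0.16 to -0.11. Cytosolic ribosomal protein genes shifted slightly the other way, with 2 of 32 higher in the libraries labelled KO, Rpl4 and Rpsa, and 30 not passing (5 adjusted over the list alone, 7 with the replicate block). Their median was 0.26, and 0.17 without the library labelled KO replicate 3 (camera adjusted p = 4.19e-08, and adjusted p = 0.591 with an estimated correlation). Hspa8, Rpl4 and Rpsa were not called without the library labelled WT replicate 1 or 3, or any 1 of those labelled KO (adjusted p up to 0.193, 0.166 and 0.199). Beside these lists, neutrophil and macrophage markers had medians of -3.91 and -1.47.

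Receptors of fatty acids and their derivatives, apart from Ffar1, were on balance lower in the libraries labelled KO. Of 17 tested members, Ffar1 rose, 5 fell and 11 did not pass (2 and 7 adjusted over the list alone, 2 and 8 with the replicate block). Gpr132 fell by 0.55 on the log2 scale and the leukotriene receptor Cysltr1 by 2.34. The median was -1.14, also with Ffar1 at its bound (camera adjusted p = 0.00427, and adjusted p = 0.585 with an estimated correlation). Among 30 genes of Gq and G protein-coupled receptor signalling, 6 rose, 5 fell and 19 did not pass (9 and 9 adjusted over the list alone, camera adjusted p = 0.807). Gnaq, an alpha subunit that couples to phospholipase C, fell by 0.61, Prkca rose by 0.96 ± 0.14, and the RGS proteins Rgs13 and Rgs16 fell by 3.53 and 2.37. The alpha subunit Gna11 and the phospholipase Plcb2 rose by 0.44 ± 0.10 and 0.53 ± 0.09 (adjusted p = 0.0362 and 0.0120). Gpr132 was not called without the library labelled WT replicate 1 or 3, or any 1 of those labelled KO (adjusted p up to 0.0856). Cysltr1 was not called without the library labelled WT replicate 1 or 3, or labelled KO replicate 2 or 3 (adjusted p up to 0.119). Gnaq was not called without the library labelled KO replicate 2 (adjusted p = 0.0564). All 16 neutrophil and all 23 macrophage markers were lower in the same comparison, with medians of -3.91 and -1.47. As medians relative to each gene's mean, the receptor list had 0.94, 0.16 and 0.62 in the libraries labelled WT replicates 1, 2 and 3, where macrophage markers had 0.94, -0.12 and 1.29.

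Cytokine genes went both ways, with 4 of 17 higher in the libraries labelled KO, 6 lower and 7 not passing (5 and 8 adjusted over the list alone, camera adjusted p = 0.336). Lta and Il10 rose by 2.49 ± 0.43 and 2.39 ± 0.45, and the chemokine Ccl5 fell by 1.53. Among 23 Toll-like receptor genes, 4 rose, 1 fell and 18 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.979). Cd180 and its partner Ly86 rose by 1.19 ± 0.11 and 0.90 ± 0.08, while the lipopolysaccharide coreceptor Cd14 fell by 1.93; 4 members fell with the replicate block. Of 22 migration genes, Ccr6 rose, S1pr2 and Cd44 fell and 19 did not pass (6 and 7 adjusted over the list alone, 7 and 7 with the replicate block, camera adjusted p = 0.979, with the median and mean below 0 and the test above). Of 24 genes that act in survival or in apoptosis, Tnfrsf13c and Tnfrsf13b rose, 4 fell, among them Bcl2l11 and Pmaip1, and 18 did not pass (2 and 5 adjusted over the list alone, 2 and 7 with the replicate block, camera adjusted p = 0.261). Lta was not called without the library labelled KO replicate 2 (adjusted p = 0.0643). Il10 and Cd44 were not called without the library labelled WT replicate 3, or any 1 of those labelled KO (adjusted p up to 0.0801 and 0.159). S1pr2 was not called without the library labelled WT replicate 1 or 3, or any 1 of those labelled KO (adjusted p up to 0.127). Bcl2l11 and Pmaip1 were not called without any 1 of the libraries labelled KO (adjusted p up to 0.0822 and 0.109).

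Metabolic lists were not called. In fatty acid and cholesterol synthesis, 4 of 30 genes rose, 1 fell and 25 did not pass (5 and 1 adjusted over the list alone, 7 and 3 with the replicate block, camera adjusted p = 0.395). Scd1, a fatty acid desaturase, rose from 171 ± 17.9 to 691 ± 294 CPM, and the sterol exporter Abcg1 fell by 1.47 on the log2 scale. In fatty acid oxidation, Hadh and Hadha rose and 23 of 25 did not pass (2 and 1 adjusted over the list alone, 2 and 4 with the replicate block, camera adjusted p = 0.395), with a median of 0.08 and a mean of -0.07. The lipid droplet gene Plin2 just missed the threshold (log2 fold change -1.93 ± 0.41, adjusted p = 0.0502) and was called with the replicate block (blocked adjusted p = 1.65e-05). Among 25 glycolysis and hypoxia genes, Ankrd37 rose, Pgam1 fell and 23 did not pass (1 and 1 adjusted over the list alone, 1 and 7 with the replicate block, camera adjusted p = 0.101). None of 31 nuclear genes of oxidative phosphorylation was called by edgeR in either fit, nor adjusted over the list alone (camera adjusted p = 0.395). For mTORC1 and amino acid genes, Ddit4 rose from 24.0 ± 2.15 to 59.0 ± 1.08 CPM, Shmt2 and Mthfd2 fell and 17 of 20 did not pass (1 and 5 adjusted over the list alone, 1 and 5 with the replicate block, camera adjusted p = 0.141). Scd1 was not called without the library labelled WT replicate 1 or 3, or labelled KO replicate 2 (adjusted p up to 0.0937). Hadh was not called without the library labelled KO replicate 1 (adjusted p = 0.0551). Hadha and Ankrd37 were not called without the library labelled WT replicate 1 or 3, or any 1 of those labelled KO (adjusted p up to 0.147 and 0.0926). Pgam1 and Shmt2 were not called without the library labelled KO replicate 1 or 2 (adjusted p up to 0.0797 and 0.0609). Mthfd2 was not called without the library labelled KO replicate 2 (adjusted p = 0.0615).

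Proliferation genes showed Ccne1 higher and Hmgb2 lower, with 28 of 30 not passing (1 and 1 adjusted over the list alone, 1 and 2 with the replicate block, camera adjusted p = 0.979). Of 16 clock genes Per1 rose and 15 did not pass (1 adjusted over the list alone, camera adjusted p = 0.979). Of 13 glucocorticoid-induced genes, Ddit4 and Per1 rose, Dusp1 fell and 10 did not pass (2 and 3 adjusted over the list alone, 3 and 3 with the replicate block, camera adjusted p = 0.979, with a median of 0.05 and a mean of -0.03). Ccne1, Per1 and Dusp1 were not called without the library labelled WT replicate 1 or 3, or any 1 of those labelled KO (adjusted p up to 0.149). Hmgb2 was not called without the library labelled WT replicate 3, or labelled KO replicate 1 or 2 (adjusted p up to 0.0940).

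Markers of other blood cells were mostly lower in the libraries labelled KO, that is, higher in those labelled WT. All 16 neutrophil markers were lower, with a median of -3.91; 3 fell and 13 did not pass, 16 fell when adjusted over the list alone and 8 with the replicate block (camera adjusted p = 5.62e-07, and adjusted p = 0.585 with an estimated correlation). The granule genes Elane, Mpo and Prtn3 fell by 2.11, 2.27 and 1.97. The neutrophil median was -2.67 without the library labelled WT replicate 1, which held 29633 counts of S100a9 against 8113 and 2546 in the other replicates labelled WT. All 23 macrophage and monocyte markers were lower, with a median of -1.47; 4 fell, Cd14, Ccr2, Fcgr1 and Ly6c2, and 19 did not pass (10 adjusted over the list alone, 20 with the replicate block, camera adjusted p = 1.96e-08, and adjusted p = 0.585 with an estimated correlation). Elane was not called without the library labelled KO replicate 2 (adjusted p = 0.0556). Mpo, Prtn3 and Ly6c2 were not called without any 1 of the libraries labelled WT, or that labelled KO replicate 2 or 3 (adjusted p up to 0.141, 0.134 and 0.159). Ccr2 was not called without the library labelled WT replicate 1 or 3, or labelled KO replicate 2 or 3 (adjusted p up to 0.147). Fcgr1 was not called without the library labelled WT replicate 1 or 3, or any 1 of those labelled KO (adjusted p up to 0.169).

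Of 18 T cell markers, Cd8b1 fell and 17 did not pass (1 and 1 adjusted over the list alone, 1 higher and 6 lower with the replicate block), with a median of -2.81 and of -1.18 without the library labelled WT replicate 1. The T cell list was called (camera adjusted p = 0.0136, and adjusted p = 0.813 with an estimated correlation), but not without the library labelled KO replicate 3 (adjusted p = 0.0525). Of 8 NK and cytotoxic markers, Ccl5, Klrd1 and Klrk1 fell and 5 did not pass (5 adjusted over the list alone, 5 with the replicate block, camera adjusted p = 0.00949, and adjusted p = 0.585 with an estimated correlation). Among 16 dendritic cell markers, Flt3, Itgax, Klrk1 and Bst2 fell, Pacsin1 and Ly6d rose and 10 did not pass (9 and 2 adjusted over the list alone, 8 and 2 with the replicate block, camera adjusted p = 0.0130, and adjusted p = 0.585 with an estimated correlation). Cd8b1 was not called without any 1 of the libraries labelled KO (adjusted p up to 0.162). Klrd1 was not called without the library labelled WT replicate 1, or any 1 of those labelled KO (adjusted p up to 0.0954). Klrk1 was not called without the library labelled WT replicate 1, or labelled KO replicate 2 or 3 (adjusted p up to 0.126). Itgax was not called without the library labelled KO replicate 2 (adjusted p = 0.0782). Bst2 and Ly6d were not called without the library labelled WT replicate 3, or any 1 of those labelled KO (adjusted p up to 0.154 and 0.110). Pacsin1 was not called without the library labelled WT replicate 3, or labelled KO replicate 1 or 2 (adjusted p up to 0.0947).

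Of 7 megakaryocyte and platelet markers, Itgb3 fell and 6 did not pass (1 adjusted over the list alone, 5 with the replicate block, camera adjusted p = 0.0159, and adjusted p = 0.608 with an estimated correlation). The call was lost without the library labelled WT replicate 3, KO replicate 1 or KO replicate 2 (adjusted p up to 0.0951), where the median went from -1.06 to -0.30, -0.52 and -0.45, and it was -1.77 without that labelled KO replicate 3. None of 17 erythroid markers was called by edgeR (0 adjusted over the list alone, 1 with the replicate block). The list did not pass (camera adjusted p = 0.201) except with the replicate block (camera blocked adjusted p = 0.00124). With the block, the list did not pass with an estimated correlation (camera blocked adjusted p = 0.673) or by fry (blocked adjusted p = 0.400). Its median of -1.50 became 0.72 without the library labelled WT replicate 3, in which Hba-a1 had 27881 counts against 2666 and 2611 in the other replicates labelled WT. Of 12 stromal and endothelial markers, Pecam1 rose and 11 did not pass (1 and 1 adjusted over the list alone, 1 and 2 with the replicate block, camera adjusted p = 0.934), with a median of 0.32 and a test direction below 0; Col3a1 had 3355 counts in the library labelled KO replicate 3 and at most 14 in any other. Pecam1 was not called without the library labelled WT replicate 1 or 3, or labelled KO replicate 1 or 2 (adjusted p up to 0.139).

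**Figure D4:**
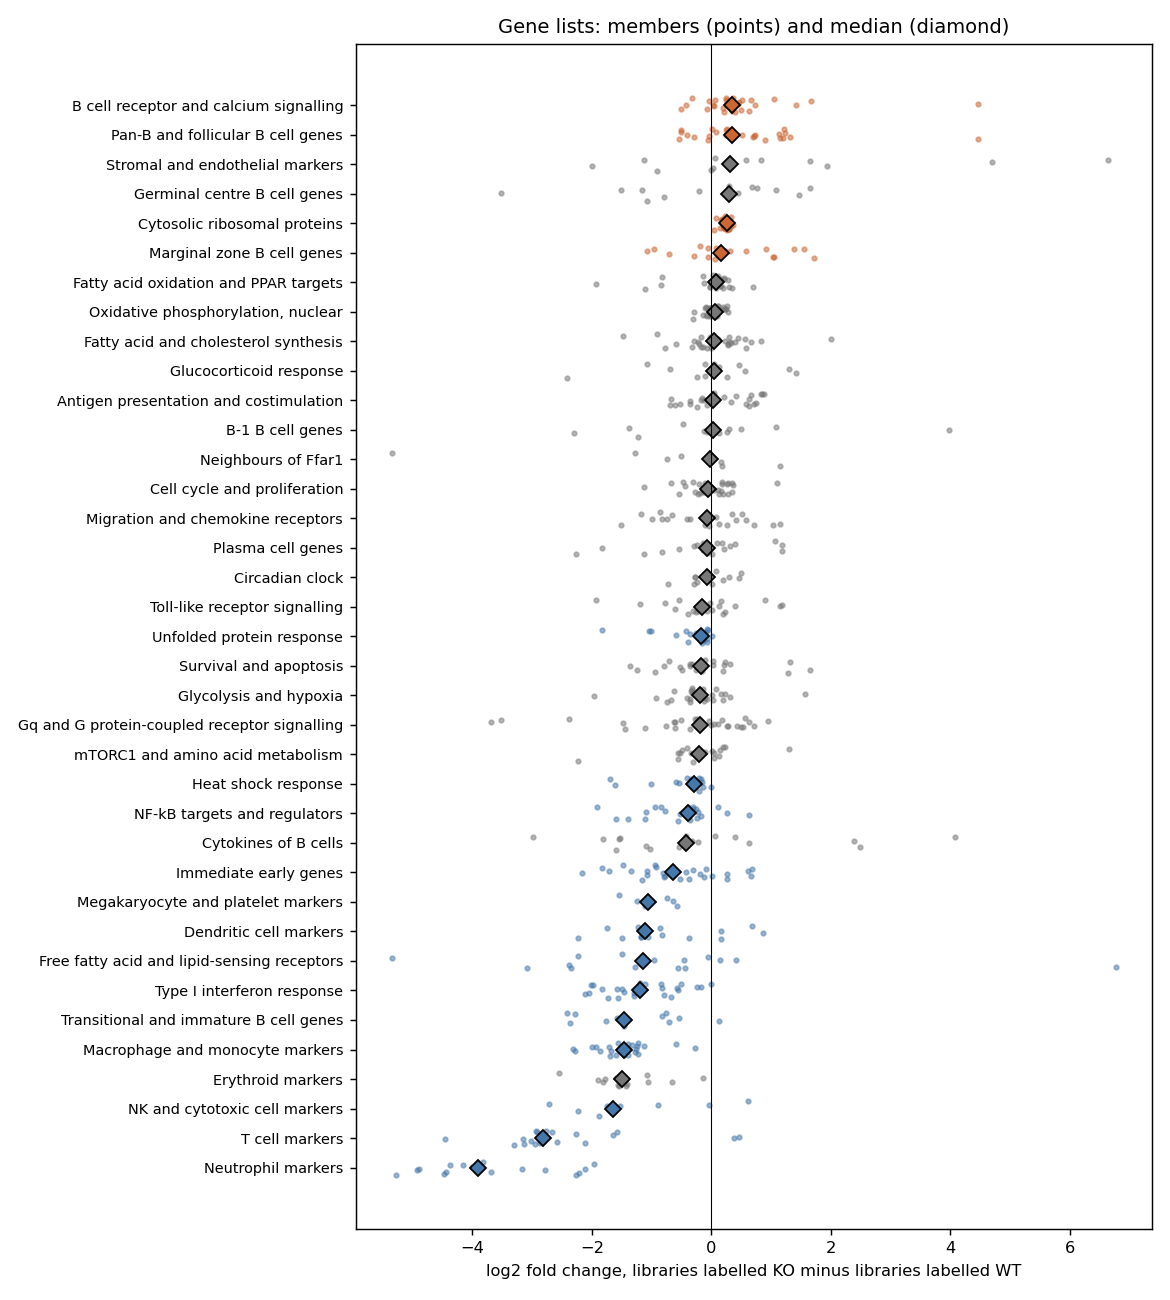
Log2 fold changes (libraries labelled KO minus labelled WT) of the tested members of 37 gene lists as points, with the median as a diamond and Ffar1 drawn at its lower bound. Lists called by camera with the preset correlation are orange where higher in the libraries labelled KO (4 lists) and blue where lower (13 lists); none was called with an estimated correlation.

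Camera with the preset correlation called 17 of 37 lists, and 0 were called with an estimated correlation (adjusted p from 0.388 upward, with 2 lists at an unadjusted p under 0.05). The estimated correlation was -7.11e-04 for the transitional list, below the preset 0.01, and 0.0127 for the marginal zone list. Both lost their calls (camera adjusted p from 6.94e-05 to 0.388 and from 0.0425 to 0.585). A higher correlation between genes therefore cannot account for the loss of the transitional call. Fry, which asks whether the genes of a list move on balance one way, called 7 lists, 6 of them shared with camera. The list it added was that of germinal centre genes (fry adjusted p = 0.0240). With the replicate block fry also called 7 lists, but not that of germinal centre genes (fry blocked adjusted p = 0.625). It then also missed the pan-B, marginal zone and transitional lists (fry blocked adjusted p = 0.0558 for each).

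At the level of transcripts, Ffar1 and Ffar3 were again among the calls. Of 31150 transcripts tested, 48 were called, 37 higher in the libraries labelled KO and 11 in those labelled WT. They belong to 44 genes, all of which were also called as genes, and no gene had calls in both directions. Of the Cd22 transcripts, 1 of 6 was called (1.23 ± 0.12, adjusted p = 0.0499). With the replicate block 0 transcripts were called by edgeR, with 2896 at an unadjusted p under 0.05, while DESeq2 without the block called 2407. Leaving out 1 library left 1 to 5 calls: 3, 5 and 2 without the libraries labelled WT replicates 1, 2 and 3, and 1, 2 and 1 without those labelled KO replicates 1, 2 and 3.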

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

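The fit without the libraries labelled WT replicate 1 and labelled KO replicate 3 together was chosen after seeing the data; the other alternatives were fixed before. Ffar1 kept its direction and its call under every alternative. All 112 named genes that were called kept their direction under every alternative, 47 of them stayed past the threshold in each fit without 1 library and 46 under every alternative run for them. The number of called genes was 2210 with DESeq2 (853 higher and 1357 lower in the libraries labelled KO), 2535 with the replicate block, 449 with the size threshold and 567 without both libraries that stand apart, against 1146; it ran from 264 to 2030 when 1 library was left out. Called lists went from 17 to 0 with an estimated correlation and to 7 with fry. Called transcripts went from 48 to 109 with no filter, 2407 with DESeq2, 0 with the replicate block and 0 without both libraries that stand apart, and ran from 1 to 5 with 1 library left out. Fits with fewer libraries have fewer samples to estimate the spread. Among simulated genes, DESeq2 made 20 false calls in 138 calls, where the main test made 3 in 118. How many of the added DESeq2 calls here are false was not tested, nor was the cause of the other differences. Col3a1 reversed when 1 library was left out (log2 fold change -1.12 to 7.22). No called list reversed. The direction of the test turned for 10 lists that were not called in the main analysis, whose medians are given on the log2 scale. With fry it turned for plasma cell (-0.072), cell cycle (-0.050), Toll-like receptor (-0.16) and glucocorticoid genes (0.048). With no filter it turned for migration (-0.11) and glucocorticoid genes (0.085), and with the stricter filter for cell cycle (-0.032) and stromal genes (1.65). With the replicate block it turned for cell cycle (-0.043), migration (-0.073), glucocorticoid (-0.11) and stromal genes (-0.18). Without both libraries that stand apart it turned for cell cycle (-0.019), oxidative phosphorylation (-0.070) and Toll-like receptor genes (-0.038). With 1 library left out it turned for all 10, with medians from 0.23 to 0.33 for germinal centre, -0.15 to 0.036 for plasma cell, -0.070 to 0.021 for cell cycle, -0.044 to 0.10 for oxidative phosphorylation, -0.14 to -0.090 for Toll-like receptor, -0.17 to 0.036 for migration, -0.089 to -0.012 for clock, -0.24 to 0.12 for glucocorticoid, -1.96 to 0.72 for erythroid and -1.20 to 0.91 for stromal genes. Among all named genes and the counts given in the report, the replicate block changed calls as stated there and ended the call of 4 named genes, Ryr1, Ret, Rag1 and Rag2, while 26 gained one. Depth limits genes near the floor of 3 counts, and the self-test recovered 20.9% of genes changed by 1.5-fold.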

Other observations

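The tests on Ffar1 and on the genes of other blood cells were chosen after the result was seen, as were the genes of the next paragraph, while the splits of the libraries were set before.

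Several further genes separated the groups clearly outside the fixed lists. The cytokine receptor gene Il9r was 161 ± 13.1 CPM in the libraries labelled WT and 16.1 ± 2.14 CPM in those labelled KO (SD, n = 3; log2 fold change -3.33 ± 0.12, SE; edgeR adjusted p = 1.38e-05), and the collagen gene Col27a1 was 111 ± 14.7 against 16.4 ± 0.82 CPM (adjusted p = 2.77e-05). Il5ra, the interleukin-5 receptor of B-1 cells and eosinophils, was higher in the libraries labelled KO, at 80.9 ± 7.91 against 10.2 ± 3.16 CPM (adjusted p = 4.17e-04). The neighbouring genes Kctd14 and Ints4 on chromosome 7 were both higher there, at 38.1 ± 3.35 against 4.54 ± 0.61 CPM and 168 ± 5.29 against 56.8 ± 2.87 CPM, while Clns1a and Ndufc2 nearby had log2 fold changes of -0.04 ± 0.09 and -0.03 ± 0.16. In the library labelled KO replicate 3, the skeletal muscle genes Myh4, Acta1 and Ckm had 3343, 3585 and 1955 counts, and Myh4 had 0 in each of the other libraries.

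With 6 libraries in groups of 3 there are 10 splits, too few for a share under 0.05. The labelled split was the 1 with the highest count in each case. It called 1146 genes and the highest of the others 0, 17 lists against 15, and 48 transcripts against 0. Of the 3 other splits that part all same-numbered libraries, the highest called 0 genes, 11 lists and 0 transcripts.

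The Ffar1 counts went against the labels in 6 of 6 libraries. One library carrying a wrong label would put 1 library out of place, which the 6 argue against. Reads running on from Cd22 would leave 447 Ffar1 counts in the libraries labelled WT at the ratio seen in those labelled KO, where 0 were seen. That expectation holds only if the Ffar1 sequence is intact in the libraries labelled WT. Since this is not known, the counts cannot decide about reads running on. Genotype labels exchanged between the groups may account for all 6, and this stays open as a hypothesis. A mutant allele that keeps or adds an Ffar1 transcript cannot be told apart from it, because the tables hold 1 Ffar1 transcript and no coverage along it.

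Genes of other blood cells were higher in the libraries labelled WT, for 95.4% of the 65 tested neutrophil, macrophage, T cell and NK markers, abundant ones such as Lyz2 (2412 ± 974 against 664 ± 200 CPM) included. If a smaller share of B cells raised every other type alike, the medians of these lists would lie close together. The neutrophil and macrophage medians lay 2.45 log2 units apart, more than the SD within either list (1.10 at most). Without the library labelled WT replicate 1 they were -2.67 and -1.39. Other types need not rise alike, so the gap cannot decide whether the share of B cells was smaller. For neutrophil markers, the library labelled WT replicate 1 alone is argued against, since their median was -2.67 (SD 0.59) without it. The T cell median went from -2.81 to -1.18 without that library, and the macrophage median from -1.47 to -1.39. Without the library labelled WT replicate 3 the erythroid median went from -1.50 to 0.72. Single libraries thus weighed heavily on some of these lists. RNA of other blood cells in the libraries labelled WT, left after negative selection, may account for these genes. Whether their share followed the genotype or the cell preparation was not tested.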
